A study of Malus domestica with 9 samples.

How the data were processed

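RNA was sequenced from the peel of apple fruit (Malus domestica) that had been grown in bags and was then exposed to light for 0, 6 or 24 h after the bags were taken off. The series holds 9 libraries, 3 per time point, described by the submitters as biological replicates. The labels do not say whether the replicates were separate fruit, trees or pools, so the p-values measure the spread between these libraries. Per the labels' protocols, total RNA was extracted with Trizol and made into Illumina mRNA libraries.

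The deposited values are FPKM (fragments per kilobase of transcript and per M mapped fragments) per gene and library, as the authors computed them. The submitters' processing notes name HISAT2 and Cufflinks. Their versions, the genome build, the annotation, the filters and the strand setting are not given in the sources used here. The table lists 46558 genes, of which 37142 were above 0 in at least 1 library. Genes are identified by apple locus identifiers alone, written here without the prefix "gene:" that each carries in the table. None of these identifiers occurs in the RefSeq gene table that was at hand (51804 genes, assembly GDT2T_hap1; 0 identifiers matched), and the deposited table does not pair them with names. For this reason the 36 gene lists on pigment synthesis, light signalling, photosynthesis, hormones and other functions, fixed as patterns on gene descriptions before the data were examined, were not run, and no gene function, coordinate or exon is given. How the authors' counting split reads between near-identical or overlapping genes is likewise not given, so values of such genes are uncertain.

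The depth behind the FPKM values was worked out from the values themselves. Within a gene, the low FPKM values of all libraries were whole multiples of 1 common step after a single factor per library, and the steps of all genes were those of a whole gene length in bases. For all 37142 genes above 0, this gave whole read counts that rebuilt the deposited FPKM to within a relative difference of 6.89e-08, and 100.0% of the positive values lay within 0.1 of a whole read. These numbers are called reads here, since the values do not show whether a unit was a read or a read pair. The procedure was tried on 6000 simulated genes and scored on those with reads in most of the libraries. It returned the right counts for 99.9% of the scored genes. Genes with reads in fewer libraries were not covered by this check, so their counts are less certain. The libraries held 15331227 to 19495791 reads in genes, and 1 read in a gene of the median length of the tested genes (1533 bases) was worth 0.0343 to 0.0404 FPKM. The denominators that the authors' FPKM contain were not these totals. They were 16.2 to 19.0 M (mega), the reads in genes made up 0.911 to 1.21 of them, and they were proportional to median-of-ratios size factors of the reads to within 0.856%. Samples are therefore compared here on a scale close to median-ratio scaling.

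FPKM are not counts, so the tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. The pseudocount of 1 makes the log2 differences of low genes smaller than those of the FPKM themselves. Genes with a mean of at least 1 FPKM over all 9 libraries were tested (25362 genes). One linear model with a mean per time point was fitted to all 9 libraries, so that the 3 groups shared 1 estimate of the spread (6 residual degrees of freedom), and the variances were moderated with an intensity trend. A gene was called in a comparison at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes and an absolute log2 difference of at least 1. All adjusted p-values in the text come from this limma model unless another fit is named. A moderated F-test with an adjusted p under 0.05 was used for any change over the 3 times. In libraries simulated for the comparison of 6 h with 0 h (25229 genes), 82 of 99 genes changed by 3-fold and 97 of 98 changed by 8-fold were called. Limma called 0 of 25032 unchanged genes, against 1257 of these at an unadjusted p under 0.05. The simulation gave every gene the same relative spread beyond counting error, and no library lay apart. At that spread an unchanged gene could hardly reach the size limit, so the 0 does not measure false calls in the real data.

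For the case that identifiers could not be paired with functions, the rule fixed beforehand was to name the 2 genes that rose most and the 2 that fell most. After the identifiers proved unmatched, this was applied to each of the 3 comparisons separately, on the log2 scale, to called genes whose libraries did not overlap between the times and whose higher mean was at least 10 FPKM, the limits that the fixed rule set for genes with a function. This gave 11 different genes. The most abundant gene was named after its values were seen. Because the comparisons of 6 h and 24 h share the 0 h libraries, 100 data sets of 9 unchanged libraries with the fitted spread were simulated for comparison with their overlap. Counting intervals are exact 95% intervals and cover counting error only. Replicates were compared for identity: no 2 libraries of a time held identical values, and the chi-square per degree of freedom of their reads ranged from 2.50 to 32.6. The values of 31.8 and 32.6 belonged to pairs with the third 24 h library, and the highest other value was 7.04. No library was thus a copy of another, and each was counted as 1 sample. This does not show that they came from separate fruit.

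The alternatives fixed beforehand were other pseudocounts (0.1 and 5), other filters (none and a mean of at least 5 FPKM), median-ratio and quantile scaling, other variance priors, the replicate number as a block, fits to the 6 libraries compared, adjusted p alone, and leaving out each library. Limma-voom on the recovered reads, limma sample weights, summed reads as the denominator and removal of the trend with gene length were added after seeing the data. Calculations outside limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. No column of the table was left out.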

Results

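The peel transcriptome of bagged apples was followed over the first day of light. Bagging keeps light from the growing fruit, so the peel stays pale or green, and taking the bag off exposes it to light. Per the series title, the study covers the period in which the peel turns from green to red. Peel was sampled at 0 h, 6 h and 24 h of light, with 3 libraries at each time. No fruit kept in bags was sampled at 6 h or 24 h, so the differences are between times, and light cannot be separated from bag removal, nor at 6 h from time of day. The comparison of 24 h with 6 h also spans different times of day, while 0 h and 24 h lie a full day apart. Changes seen at 6 h alone therefore cannot be told apart from a daily rhythm. In units of M (mega) reads, the reads in genes averaged 16.6 ± 1.29 (SD, n = 3) at 0 h, 17.4 ± 0.687 (SD, n = 3) at 6 h and 18.3 ± 1.13 (SD, n = 3) at 24 h.

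The 3 times were clearly separated. Across the 25362 tested genes, libraries of the same time correlated at r = 0.966 to 0.992 on the log2(FPKM + 1) scale, and libraries of different times at r = 0.809 to 0.863. These are correlations across genes, which are not independent replicates. The first principal component, with 50.9% of the variance, ordered the libraries from 0 h over 6 h to 24 h. The second, with 39.0%, set the 6 h libraries apart from both other times. The third, with 5.33%, separated the third 24 h library from the other 24 h libraries. That library had the highest residual spread of the 9, with an SD of 0.328 log2 units against 0.123 to 0.195 in the others. By the moderated F-test of limma, 18431 of the tested genes (72.7%) changed over the 3 times at an adjusted p under 0.05, and 7773 genes (30.6%) were called in at least 1 of the 3 comparisons between times.

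**Figure D1:**
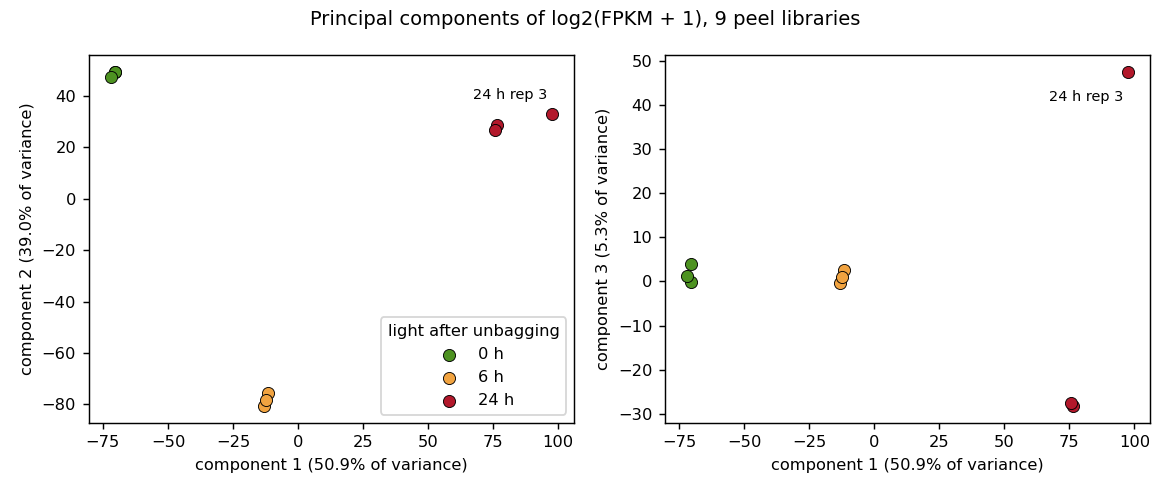
Scores of the 9 peel libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2(FPKM + 1), with the percent of variance on each axis and each library as a point coloured by hours of light. The 3 times form separate groups, and the third 24 h library lies at 47.5 on component 3, against -28.2 and -27.6 for the other 24 h libraries.

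The comparison of 6 h with 0 h asks which genes changed early after unbagging. Of the tested genes, 2374 were higher and 1565 lower at 6 h. These counts were 1366 and 680 with a pseudocount of 5, and 2847 and 2112 with 0.1. The rises reached further than the falls: 778 genes rose by more than 4-fold on the log2(FPKM + 1) scale and 133 by more than 16-fold, against 205 and 3 among the genes that fell. The median change was 1.62 log2 units in the genes that rose and -1.33 in those that fell. MD10G1328100 rose most. It stood at 0.187 ± 0.282 FPKM (SD, n = 3) at 0 h, where 12 of its 13 reads came from 1 library, and at 1402 ± 88.8 FPKM (SD, n = 3) at 6 h. Its log2 difference was 10.23 (SE 0.182, limma adjusted p = 7.27e-10). MD02G1079200 went from 2.19 ± 0.174 to 425.4 ± 79.5 FPKM (SD, n = 3 each), a log2 difference of 7.04 (SE 0.128, limma adjusted p = 7.27e-10). On the log2(FPKM + 1) scale the genes that fell most were MD00G1167000, from 63.7 ± 10.4 to 1.31 ± 0.330 FPKM (SD, n = 3 each), and MD17G1271400, from 23.8 ± 2.29 to 0.312 ± 0.0360 FPKM (SD, n = 3 each). Their log2 differences were -4.80 (limma adjusted p = 6.41e-09) and -4.23 (limma adjusted p = 2.16e-09). The excess of rises depended on the scale: 60.3% of the called genes were higher at 6 h on the deposited scale, 55.6% with summed reads as the denominator and 52.5% after quantile normalization.

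The comparison of 24 h with 0 h gives the state after a day of light. It held the largest number of called genes of the 3 comparisons, 3010 higher and 2004 lower at 24 h. These counts were 1978 and 719 with a pseudocount of 5, and 3585 and 2881 with 0.1. With the pseudocount of 1, 1076 genes rose and 206 fell by more than 4-fold. MD10G1328100 was again the gene that rose most, at 1107 ± 241 FPKM (SD, n = 3) and a log2 difference of 9.87 (SE 0.182, limma adjusted p = 2.51e-10). MD08G1168600 rose from 1.97 ± 0.468 FPKM at 0 h to 999.4 ± 303 FPKM at 24 h (SD, n = 3 each), with 75.7 ± 14.8 FPKM at 6 h in between, and its log2 difference at 24 h was 8.37 (SE 0.214, limma adjusted p = 1.11e-09). MD16G1025500 fell from 46.4 ± 2.28 FPKM to 0.171 ± 0.00723 FPKM (SD, n = 3 each), with a log2 difference of -5.34 (limma adjusted p = 1.2e-07). Only 3 reads of it were left at 24 h, 1 in each library, against 863 at 0 h, and the ratio of these reads, each divided by the summed FPKM denominators of its 3 libraries, was 272 with an exact 95% counting interval of 92.8 to 1320. MD14G1085300 fell from 201.8 ± 13.0 FPKM over 20.5 ± 0.835 FPKM at 6 h to 6.56 ± 0.0924 FPKM (SD, n = 3 each), a log2 difference of -4.74 at 24 h (limma adjusted p = 1.85e-10). The share of higher genes depended on the scale: 60.03% of the called genes were higher at 24 h on the deposited scale, and 45.8% with each library's summed reads as the denominator, which moved the median of all tested genes by -0.183 log2 units. The third 24 h library, which lay apart from the others, entered this comparison, and without it 4619 genes were called in place of 5014.

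**Figure D2:**
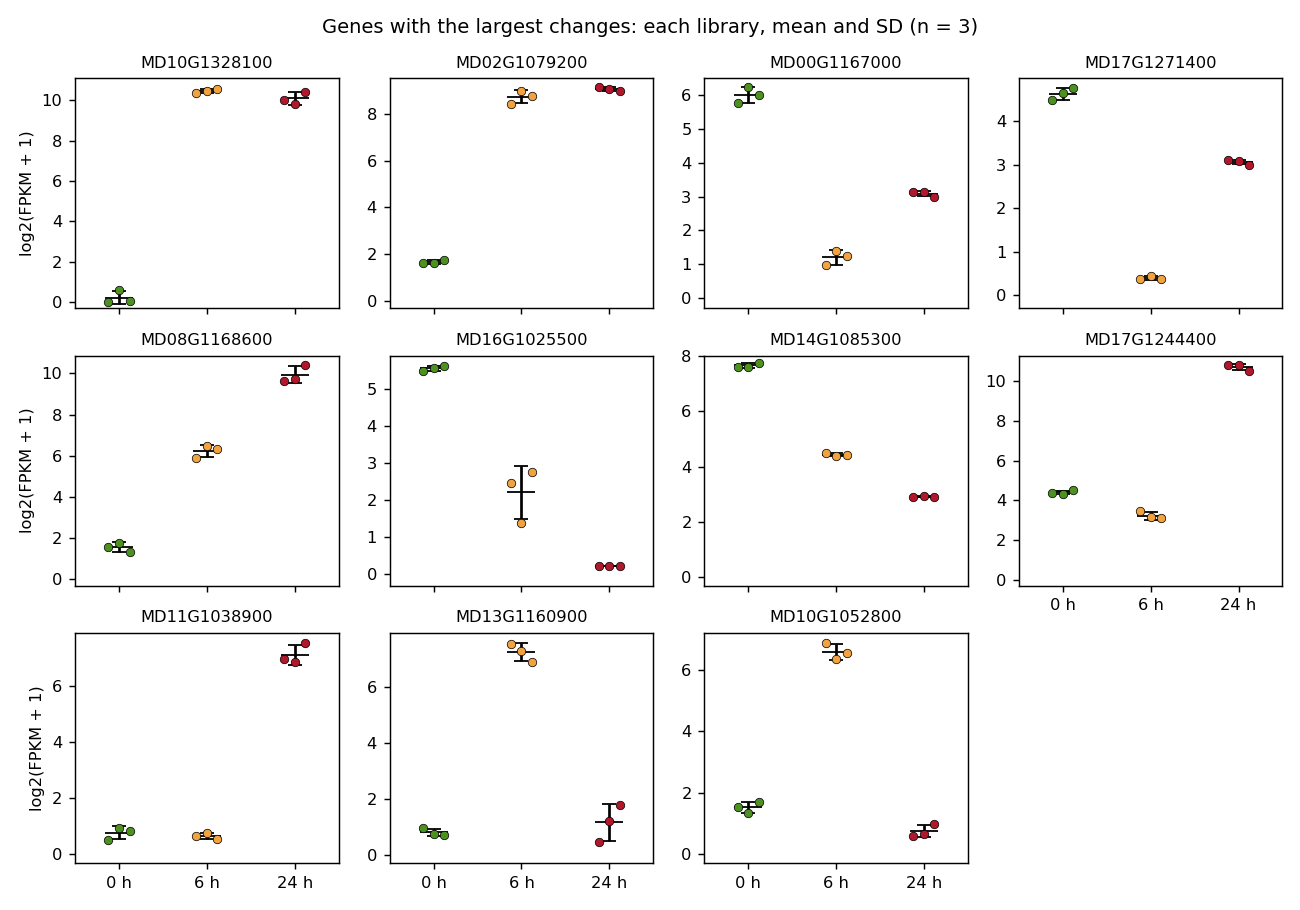
Expression of the 11 genes named for the 3 comparisons, as log2(FPKM + 1) at 0 h, 6 h and 24 h of light, with libraries as points, means as horizontal lines and SDs as whiskers (n = 3). MD10G1328100 and MD02G1079200 were high at both light times, MD13G1160900 and MD10G1052800 were high at 6 h, and MD17G1244400 and MD11G1038900 were high at 24 h.

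The comparison of 24 h with 6 h tests the change between the light times themselves, which also differ in time of day. In it 2197 genes were higher and 1976 lower at 24 h. These counts were 1397 and 1001 with a pseudocount of 5, and 2618 and 2604 with 0.1. On the log2(FPKM + 1) scale the falls were deeper than those seen against 0 h, with 520 genes lower by more than 4-fold and 45 by more than 16-fold. MD17G1244400 was at 8.42 ± 1.33 FPKM at 6 h and at 1715 ± 187 FPKM at 24 h (SD, n = 3 each), a log2 difference of 7.51 (SE 0.119, limma adjusted p = 2.81e-10). At 6 h it had fallen below its 0 h level of 20.2 ± 1.27 FPKM (SD, n = 3), with a log2 difference of -1.18 (limma adjusted p = 1.9e-05). MD11G1038900 was at 0.574 ± 0.128 FPKM at 6 h and at 139.1 ± 36.7 FPKM at 24 h (SD, n = 3 each), with a log2 difference of 6.45 (limma adjusted p = 3.41e-09). The genes that fell most between these times had risen before. MD13G1160900 went from 0.737 ± 0.158 FPKM at 0 h to 154.1 ± 33.6 at 6 h and 1.38 ± 1.04 at 24 h (SD, n = 3 each), and its fall was -6.11 log2 units (limma adjusted p = 7.22e-08). MD10G1052800 went from 1.89 ± 0.362 to 97.6 ± 18.2 and 0.684 ± 0.247 FPKM (SD, n = 3 each), and its fall was -5.87 log2 units (limma adjusted p = 3.1e-09). With summed reads as the denominator, the median of all tested genes moved by -0.129 log2 units in this comparison. The share of higher genes among the called ones was then 44.3%, against 52.7% on the deposited scale, and without the third 24 h library 3938 genes were called in place of 4173.

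The calls of the 3 comparisons sorted the genes by the time of their change. A group of 1022 genes was higher and a group of 809 lower than at 0 h at both light times. With a pseudocount of 5 these groups held 518 and 357 genes, and with 0.1 they held 1391 and 1051. Which of these groups was larger depended on the scale, with 895 higher and 1051 lower after quantile normalization, and 848 and 1043 with summed reads as the denominator. The first of these groups had median levels of 4.06, 21.8 and 25.7 FPKM at 0 h, 6 h and 24 h, and the second of 15.4, 4.20 and 4.10 FPKM. Within the first group, 219 genes were called higher and 171 lower at 24 h than at 6 h. MD10G1328100 and MD02G1079200 belonged to this group and were called in neither direction between 6 h and 24 h.

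A transient rise was the next pattern, which cannot be told apart from an effect of the time of day at 6 h. It was found in 918 genes, which were higher at 6 h than at both 0 h and 24 h and were not called between 24 h and 0 h. Their median levels were 3.21 FPKM at 0 h, 16.5 at 6 h and 2.88 at 24 h. MD13G1160900 and MD10G1052800 were among them. A transient fall was found in 254 genes, with median levels of 14.7, 4.43 and 16.05 FPKM. These counts depended on the pseudocount and the filter: the transient fall ranged from 89 genes with a pseudocount of 5 to 424 with 0.1 and 429 by limma-voom on the recovered reads, and the transient rise fell to 565 with a pseudocount of 5 and 579 with a mean of at least 5 FPKM.

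A late rise was found in 1296 genes. Their level was higher at 24 h than at both 0 h and 6 h without a call at 6 h, with median levels of 5.67, 5.84 and 26.5 FPKM. MD11G1038900 was among them. The late rise held 954 genes with a pseudocount of 5 and 1018 with a mean of at least 5 FPKM. It held 1089 with summed reads as the denominator and 1371 by limma-voom on the recovered reads. A late fall was found in 393 genes, with median levels of 12.5, 13.4 and 4.19 FPKM. Its count was unstable, with 104 genes at a pseudocount of 5, 757 at 0.1, 787 by limma-voom on the recovered reads and 594 with summed reads as the denominator. Without the third 24 h library it was 266, and without the first or second 575 and 584. Other genes changed in opposite directions at the light times. The 63 genes that were lower than at 0 h at 6 h and higher at 24 h included MD17G1244400, and 47 genes were higher at 6 h and lower at 24 h.

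**Figure D3:**
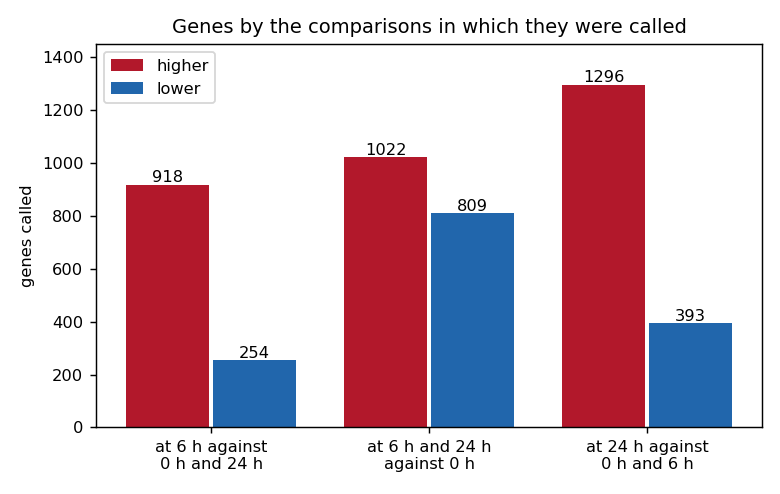
Number of genes by the comparisons in which they were called, higher in red and lower in blue, for genes that differed at 6 h from both other times (left), at both light times from 0 h (middle) and at 24 h from both other times (right). On the deposited scale with a pseudocount of 1, the late rise held 1296 genes and the transient fall 254.

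The early and late changes overlapped in part. Of the genes higher at 6 h, 43.0% were also called higher at 24 h, and of those lower at 6 h, 51.7% were also called lower. Independent lists of these sizes would share 281.7 genes in the first case and 123.7 in the second. In 100 simulations of unchanged libraries that share the 0 h controls, the mean overlap was 0 and 0.01 genes. Unchanged libraries give almost no calls with this rule, so these values do not show how far the shared controls raise the overlap of the real lists. Across genes the log2 differences at 6 h and 24 h correlated at r = 0.523, while the shared controls alone gave r = 0.5 in the simulations. Their covariance was 0.444, against 0.0135 in the simulations, a difference of 0.430. The simulations held only noise around 1 mean per gene. They leave out that both real differences also share the true 0 h level of each gene. The difference in covariance therefore does not measure a response common to 6 h and 24 h. Part of the overlap may come from the shared 0 h libraries, which were not split, since 3 libraries do not leave 2 for each comparison.

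Some genes went from nearly no reads to clear expression. At 0 h, 26 genes had at most 3 reads over the 3 libraries together and reached a mean of at least 10 FPKM at 6 h, with a median of 30.2 FPKM. For 24 h this held for 20 genes, with a median of 26.4 FPKM, and 3 genes were in both sets. In the opposite direction, MD16G1025500 was the 1 gene that had at least 10 FPKM at 0 h and at most 3 reads at 24 h, and no gene met this rule at 6 h.

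The most abundant transcripts together took a smaller share of expression at 6 h and 24 h than at 0 h. The 10 highest genes of each library made up 14.9% ± 0.716 of the summed FPKM at 0 h, 9.88% ± 0.776 at 6 h and 10.2% ± 1.45 at 24 h (SD, n = 3 each). Among the 10 genes highest by mean FPKM, the share fell most in the highest gene, described below, and in the next one. The latter held 2.49%, 1.07% and 1.71% at 0 h, 6 h and 24 h. Most of the 10 had a lower share at each light time than at 0 h, but some had a higher one. In 1 of these it was 0.356%, 0.988% and 0.592%. MD12G1187100, singled out after its values were seen, was the highest gene at every time. It had 42660 ± 4580 FPKM at 0 h, 23800 ± 3531 at 6 h and 22550 ± 2537 at 24 h (SD, n = 3 each), which is 6.42%, 3.55% and 2.97% of the summed FPKM. Its log2 differences against 0 h were -0.85 and -0.92, and it was not called in either comparison (limma adjusted p = 0.472 and 0.41). The variance trend gave it an SE of 0.92. Without the trend the limma adjusted p were 0.000743 and 0.000386, and without the third 24 h library they were 0.00831 and 0.00606, while over all alternatives they ran up to 1. Leaving out that library also brought its log2 difference at 24 h to -1.01, past the size limit for a call.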

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

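The results below are those whose change against 0 h differed between 6 h and 24 h. This was judged by the comparison of 24 h with 6 h itself, a planned test, and no test in this part was chosen after its result was seen. The named genes, however, were picked as the largest changes in these same libraries. That choice favours a return of genes extreme at 6 h and a further change of genes extreme at 24 h. MD10G1328100 and MD02G1079200 were not called in this comparison and are not listed. That comparison called 4173 genes. Among the genes named for the comparisons with 0 h, MD08G1168600 rose further after 6 h, by 3.68 log2 units (SE 0.214, limma adjusted p = 3.12e-07). MD16G1025500 and MD14G1085300 fell further, with log2 differences of -1.99 (limma adjusted p = 0.000198) and -1.51 (limma adjusted p = 1.09e-07). MD00G1167000 and MD17G1271400, the genes that fell most at 6 h, had partly recovered by 24 h, with log2 differences of 1.89 (limma adjusted p = 1.9e-06) and 2.67 (limma adjusted p = 1.74e-08), and both were still lower than at 0 h.

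Other splits of the libraries were tried for each comparison. In each comparison of 2 times the real split was the 1 of 10 splits with the most genes. It gave 3953 genes for 6 h against 0 h, 4962 for 24 h against 0 h and 4133 for 24 h against 6 h in limma fits to the 6 libraries, and the highest other split gave 0, with at most 189, 408 and 413 genes at an unadjusted p under 0.05. With 10 splits the share cannot fall under 0.1. For the F-test over the 3 times, the real split was the 1 of 100 drawn splits with the most genes, 18431 against 5396 in the highest other split. This argues against a chance split, within the limit that 100 splits set. The other splits mix the times and still hold the differences between them, so they are not data without change.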

How the results depend on the processing

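Fits on the recovered reads, with sample weights, with summed reads as the denominator and with the length trend removed were chosen after seeing the data. No gene called both as reported and under an alternative had opposite directions. Such a reversal was hardly possible, since a reported call needs an absolute log2 difference of at least 1 and the refits use mostly the same values. The alternatives planned for the gene lists were not run, since no gene could be assigned to a list. With a pseudocount of 5 the counts fell to 2046 genes at 6 h against 0 h, 2697 at 24 h against 0 h and 2398 at 24 h against 6 h, and 875 genes were shared between the 6 h and 24 h calls in place of 1831. A larger pseudocount shrinks the differences of low genes by construction. It also raised the share of higher genes at 24 h against 0 h from 60.03% to 73.3%. With adjusted p alone, 12954, 14958 and 12605 genes were called. Limma-voom on the recovered reads called 5085, 6627 and 5333. The transient fall (254 genes) ranged from 89 to 429 over the settings and the late fall (393 genes) from 104 to 787, and the transient rise (918 genes) fell to 565 with a pseudocount of 5 and 579 with a mean of at least 5 FPKM, which tests fewer genes. Leaving out 1 library at a time gave 3890 to 3989, 4619 to 5378 and 3938 to 4485 genes in the 3 comparisons. Without the third 24 h library 4619 genes were called at 24 h against 0 h, and 4272 of these were among the 5014 of the full set. The falls changed more than the rises, with 2943 higher and 1676 lower, against 3010 and 2004 in the full set. The replicate numbers did not pair the libraries: same-numbered libraries of different times deviated together at r = -0.063 to 0.076, and 1 of 9 correlated best with its own number at both other times. With the number as a replicate block 3941, 5019 and 4175 genes were called. The 11 genes named by rule passed in 276 of 276 refits, with limma adjusted p up to 7.1e-06. They were chosen as the largest called changes of the same data, and some refits left out no compared library, so this does not test them. Their sizes moved with the pseudocount and by limma-voom: MD17G1271400 at 6 h against 0 h was -2.43 with a pseudocount of 5, -5.85 with 0.1 and -6.20 by limma-voom (-4.23 as reported), and the latter settings put it past MD00G1167000 (-5.51 and -5.60). MD16G1025500 at 24 h against 0 h was -3.31, -7.42 and -7.50 (-5.34), and MD10G1328100 at 6 h against 0 h was 8.08, 12.71 and 13.80 (10.23). MD12G1187100 passed at 24 h against 0 h with sample weights (-1.02), with summed reads as the denominator (-1.14) and without the third 24 h library (-1.01), and quantile normalization fixed its difference at 0, since it is the highest gene in every library. Depth limits low genes: at the median length 1 read was worth 0.0343 to 0.0404 FPKM.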

Other observations

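The tests of length, depth, labels and time course for the third 24 h library were chosen after it was seen to lie apart, while the quantile test and both tests of neighbouring genes were set before their results were seen.

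Genes with neighbouring identifiers changed together, if the digits after MD are taken as the chromosome and the last number as the order along it (MD00 left out). At 24 h against 0 h, 864 of 24551 adjacent pairs of tested genes were called in the same direction, against 500 on average and 564 at most in 1000 permutations of the calls, which argues against chance placement (p = 0.001, the smallest these permutations can give). The excess was 1.73-fold for adjacent genes, 1.25-fold for the next but one and 0.989-fold at 200 positions, and for adjacent genes it was 2.02-fold at 6 h against 0 h and 1.98-fold at 24 h against 6 h. A candidate explanation is that copies of one gene lie side by side: co-called pairs had lengths within 10% of each other in 13.9% of cases and other adjacent pairs in 10.8%, a ratio of 1.29 (Fisher's exact test, two-sided, p = 0.00532), which lies between the limits set for and against it. Shared regulation of unrelated neighbours and reads split between similar copies cannot be told apart from it, because no sequence or alignment was at hand.

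The third 24 h library differed from the other 24 h libraries along the expression scale, with a median deviation from -0.0999 log2 units in the lowest decile of expression to 0.343 in the highest, a trend that accounted for 9.52% of the variance of the deviation. A distortion by level alone is argued against as the whole cause, since after quantile normalization its residual spread was still 1.61 times that of the other 24 h libraries (1.69 times before). Both ratios are held down because the residuals were taken from a mean that includes this library. Gene length accounted for 0.119% of the variance, and the library was not shallow, with 19.5 M (mega) reads in genes against a median of 17.3 M. Even so, it had the fewest genes above 0, 31745 against 32152 to 33270 in the others. The reads in genes of this library made up 1.21 of its FPKM denominator, against 1.02 and 1.03 in the other 24 h libraries. Its mean correlation with the 24 h libraries exceeded its highest correlation with another time by 0.123, which argues against a mixed-up time label, and its deviation followed the change from 0 h to 24 h at r = 0.0977 across genes, which argues against more of the same changes as the whole cause, although it lay further from 0 h on the first principal component (97.6 against 76.5 and 75.8). A later stage with other changes, a difference between the sampled fruit, RNA quality, base composition and admixed tissue stay open and were not tested, since no sequences, gene names or later time points were at hand.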
